A study of Homo sapiens with 12 samples.

How the data were processed

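RNA of CD4+ CD25- T cells of both cord and peripheral origin, cultured with IL-2 and with or without progesterone and TGFb1, was measured on 12 whole-genome arrays. Per the labels, total RNA was extracted with Trizol and a column kit and labelled as biotinylated cRNA. Per the submitters' processing notes, the deposited values are intensity signals that the authors summarised per probe set with MAS5, whose version is not given in the sources used here. The values were checked to be positive, not whole and on a linear scale, with medians of 7.87 to 11.6 and largest values of 11782 to 16817 per array. The scaling target is not stated in the sources used here. Detection calls and image files were not used here. No coordinates are given, since no genome build was used.

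The table held 54675 probe sets, of which 62 were array controls, 41091 were assigned to 1 gene, 1801 to several genes and 11721 to none. The probe sets with 1 gene covered 19775 genes, and 41037 of them matched a symbol of the gene reference. No array pair was identical. The mean signal, trimmed by 2% at each end, ranged from 38.3 to 76.0, a ratio of 1.99. A rule fixed in advance called for rescaling above a ratio of 1.25, so each array was scaled to the median trimmed mean of 46.9, with factors of 0.617 to 1.23. An offset of 2, which is 5% of that mean rounded to a whole number, was added before log2. Probe sets with a mean scaled signal of at least 9.38, 20% of that mean, were kept. For each gene the probe set with the highest mean signal was used, and 11934 genes were tested. The comparisons, lists, naming rule and first set of other settings were chosen before the data were examined. The number of arrays limits the precision.

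Linear models were fitted to all 12 arrays with limma 3.58.1 in R 4.3.3, with terms for blood and treatment (7 residual degrees of freedom), moderated variances and a trend of variance on signal. A second model let the treatments act differently by blood (5 residual degrees of freedom) and gave the blood interactions and the differences within each blood. P-values were two-sided and adjusted over all genes tested by the Benjamini-Hochberg method, with a threshold of 0.05. Cord blood had 1 array per treatment, which was assumed to vary like the peripheral arrays. The model tests were taken from limma alone, and the other splits of the arrays in the closing section serve as the check by permutation. Lists of genes were tested with limma's camera at a preset correlation of 0.01 between genes. There were 21 lists of gene programmes and 11 of cell type markers, 32 in all, adjusted together. Camera with an estimated correlation and fry, which tests whether the genes of a list move on balance in one direction, were run beside it. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

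Genes were named by a fixed rule. It took the 10 largest increases and the 10 largest decreases past the threshold that moved the same way in every matched comparison. With fewer than 5 genes past the threshold in a direction, it took the 5 with the most extreme moderated statistic that moved alike, as values and not as changes. It added up to 4 members per list past the threshold over all genes, or failing that up to 2 adjusted over the list alone, and a short set of genes regardless of their values. Some of that set had no named probe set and were not analysed here, and others had too low a signal to be tested. Genes that can tell one person from another were never named. Genes outside the rule are said to have been chosen after their values were seen.

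That first set held a block for the culture sets, quantile normalization, offsets of 0.469 and 9, no signal filter or one at 28.2, averaging of the probe sets of a gene, no variance trend, the interaction model, peripheral arrays alone, each array left out in turn, camera with an estimated correlation and fry. Chosen after seeing the data were signals as deposited, cyclic loess, leaving out both arrays that stood apart, and peripheral arrays alone with the block.

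The fits were tested on simulated data in which 200 of the 11934 genes were shifted by a known amount, in 3 runs. For progesterone, 68.7% of the genes shifted 2-fold and 93.0% of those shifted 4-fold were recovered, with 8.14% false among the calls. For TGFb1 the shares were 68.7%, 94.3% and 6.50%. For cord against peripheral blood they were 64.3%, 94.3% and 4.23%, and for progesterone without TGFb1 32.7%, 86.7% and 3.50%. For the blood by progesterone interaction they were 3.00%, 53.0% and 7.18%. A shifted list was called in 3 of 3 runs in each of these comparisons. Simulated noise was independent between genes, whereas the shifted list, the interferon response genes, had an estimated correlation of 0.692 in the first model. It also held no differences between culture sets. The shares recovered hold for such data only, and the list calls do not show how camera acts on correlated lists.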

Results

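Gene expression was measured on 12 whole-genome arrays hybridised with RNA of human CD4+ CD25- T cells, helper T cells that lack the alpha chain of the IL-2 receptor at their surface when isolated. The cells came from umbilical cord blood or from peripheral blood. They were kept for 5 to 6 days with IL-2 at 100 U/mL, a growth factor for T cells, and received either nothing more, progesterone at 2 µg/mL, TGFb1 at 150 pg/mL, or progesterone and TGFb1 together. Progesterone is a steroid hormone of pregnancy, and TGFb1 is a cytokine that steers T cells towards regulatory and other fates. Cord blood gave 1 array for each of the 4 treatments and peripheral blood gave 2, so that the arrays formed 1 cord set and 2 peripheral sets of 4 treatments each. Nothing in the labels says that replicates came from separate donors or cultures, so the p-values measure only the spread between arrays. The number of arrays limits the precision of every value.

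Levels are scaled array signals. Differences are log2 differences of the signal plus a small offset, with their standard error (SE), and are compressed for genes of low signal. For the treatments, a matched pair is an array with and an array without the treatment that share blood, number and the other treatment, which gives 6 pairs. On the first principal component (32.3% of the variance) the 4 cord arrays lay apart from the 8 peripheral arrays, and on the second the arrays with progesterone lay apart from those without. Peripheral arrays of one treatment correlated at 0.929 to 0.954. Both peripheral arrays labelled progesterone 1 and TGFb1 2 stood apart on an RNA quality measure, the ratio of actin signals at the 5′ and 3′ ends (0.971 and 1.13, against 0.337 to 0.639 on the other 10 arrays), and carry that mark in each comparison that uses them.

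The first question of the series was which T cell genes progesterone regulates. With progesterone, 109 of 11934 genes differed, of which 70 rose and 39 fell. HIC1, a transcriptional repressor, rose most, by 4.15 ± 0.33 (adjusted p = 3.09e-05), and was higher in 6 of 6 matched pairs. Its mean signal in the peripheral cultures was 185 ± 71.8 (SD, n = 4) with progesterone and 13.6 ± 6.36 (SD, n = 4) without. FUT7, the fucosyltransferase that completes selectin ligands on T cells, fell by 4.88 ± 0.65 (adjusted p = 0.00218) and was lower in 6 of 6 pairs. ITGA4, the alpha 4 integrin chain of gut and tissue homing, rose by 1.84 ± 0.16 (adjusted p = 4.62e-05, 6 of 6 pairs).

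Among the 10 largest increases of genes higher in every matched pair were also NAPSA, an aspartic protease (3.78 ± 0.55, adjusted p = 0.00463), and LZTFL1, a regulator of ciliary transport (3.09 ± 0.30, adjusted p = 1.63e-04). QPRT, an enzyme of NAD synthesis (2.42), was another. EVI5 (2.10), COXFA4L3 (2.07), the transcriptional repressor GFI1 (1.99), the vitamin D receptor VDR (1.99) and the phospholipase PLAAT3 (1.90) completed this group, all higher in 6 of 6 pairs. Among genes lower in every matched pair, the largest decreases beside FUT7 were in TGFBR3, a co-receptor of TGFb (-1.58), and the cytokine IL6 (-1.56). The IL6 receptor chain IL6R (-1.52), BCAT1, an enzyme of branched-chain amino acid breakdown (-1.55), and the transcription factor BATF3 (-1.55) were also in this group. TMEM213 (-1.52), RNFT2, the cell cycle inhibitor CDKN2A (-1.49) and the collagen receptor MRC2 (-1.48) followed, all lower in 6 of 6 pairs, with adjusted p between 2.96e-04 for BCAT1 and 0.0366 for RNFT2.

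Of the 21 measured Treg genes, which mark regulatory T cells, 1 rose over all genes tested, IL2RA, the IL-2 receptor alpha chain CD25 (0.82 ± 0.18, adjusted p = 0.0462, 5 of 6 pairs). The other IL2RA probe set differed by only 0.11 ± 0.22, so this call rests on 1 probe set. Adjusted over the list alone, 4 rose and 1 fell, and the list was higher as a whole (median 0.37, camera adjusted p = 0.00338; adjusted p = 0.389 with an estimated correlation). FOXP3, the master regulator of these cells, differed by 0.29 ± 0.38 (adjusted p = 0.877, higher in 3 of 6 pairs), and CTLA4, an inhibitory receptor, by 0.61 ± 0.30 (adjusted p = 0.495, higher in 4 of 6). Of 15 Th1 genes, which mark interferon-gamma-producing helper cells, 1 fell, LTA, the cytokine lymphotoxin alpha (-1.38 ± 0.16, adjusted p = 7.11e-04, lower in 6 of 6 pairs). Adjusted over the list alone 5 fell and 1 rose, and the list was lower as a whole (median -0.24, camera adjusted p = 0.00621; adjusted p = 0.36 with an estimated correlation). IFNG itself differed by -0.96 ± 0.25 (adjusted p = 0.101, lower in 5 of 6 pairs) and the Th1 regulator TBX21 by -1.18 ± 0.33 (adjusted p = 0.117).

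All 24 measured interferon response genes had higher means with progesterone (median 0.64, camera adjusted p = 6.39e-15; adjusted p = 0.389 with an estimated correlation). None passed over all genes tested, where limma gave IFIT1 1.20 ± 0.32 (adjusted p = 0.103) and EPSTI1 0.81 ± 0.22 (adjusted p = 0.105), and 18 rose when adjusted over the list alone. Of 18 homing receptors, ITGA4 and the chemokine receptor CXCR6 (1.66 ± 0.33) rose, 4 rose when adjusted over the list alone, and the list was higher (median 0.24, camera adjusted p = 0.0106; adjusted p = 0.36 with an estimated correlation). Heat shock genes were lower (median -0.22, camera adjusted p = 0.0146; adjusted p = 0.36 with an estimated correlation), and 1 of 11 fell, the chaperone HSPH1 (-0.72 ± 0.13); adjusted over the list alone 1 rose and 1 fell. The 32 cell cycle genes were lower as a list by a small margin (median -0.13, camera adjusted p = 0.0106; adjusted p = 0.521 with an estimated correlation), with 0 members past the threshold in limma or adjusted over the list alone, and the proliferation marker MKI67 differed by 0.28 ± 0.12 (adjusted p = 0.412), with its 3 other probe sets at -0.18, 0.02 and -0.15.

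Among 13 cytotoxic genes, GZMB (1.68 ± 0.28), NKG7 (1.19 ± 0.21) and PRF1 (1.13 ± 0.21), which serve the killing granule, rose, while GZMK, a granzyme of memory cells, fell by 1.52 ± 0.29 and was higher in 1 of 6 pairs. Adjusted over the list alone, 5 rose and 2 fell, and the list as a whole did not pass (camera adjusted p = 0.173). The Th2 genes GFI1 and NFIL3 (0.66 ± 0.14) rose among 9 measured, and the same 2 did so adjusted over the list alone. This list had a median of -0.03, a mean of 0.31 and a test pointing up (camera adjusted p = 0.173). RORA, a nuclear receptor of Th17 cells, rose (0.79 ± 0.17) while IL6R fell, which left the other 13 of 15 Th17 genes short of the threshold. Adjusted over the list alone, 1 rose and 4 fell (camera adjusted p = 0.265). TNFSF14, a cytokine of activated T cells, fell by 1.17 ± 0.23. Of 20 IL-2 and STAT5 response genes 3 rose and 1 fell, and 5 and 2 adjusted over the list alone. This list had a median of -0.13 and a mean of 0.03 and did not pass (camera adjusted p = 0.818). The glycolytic enzyme ALDOC rose (0.86 ± 0.17) and the other 23 glycolysis and hypoxia genes did not pass.

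Of 23 steroid receptor response genes 1 rose, TSC22D3, a classical glucocorticoid-induced gene (1.498 ± 0.24, adjusted p = 0.00851, 6 of 6 pairs). FKBP5, another common target of steroid receptors, differed by -0.13 ± 0.14 (adjusted p = 0.824), and the list did not pass (median -0.13, camera adjusted p = 0.106); adjusted over the list alone 2 rose and 4 fell. The glucocorticoid receptor NR3C1 differed by 0.40 ± 0.14 (adjusted p = 0.249). GATA3 (0.16), ITGAE (0.19), SMAD7 (0.04), IL6ST (-0.25) and IL17F (-0.39) did not pass. No marker list of another cell type passed; the nearest was that of B cells (camera adjusted p = 0.0624), in which IGHM, the heavy chain of IgM, rose (0.94 ± 0.16), and the dendritic cell chemokine CCL17 differed by -0.88 ± 0.32.

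In all, 6 of 32 lists passed by camera, 0 of them with an estimated correlation and 0 by fry. The number of genes was 25 without a variance trend and 27 to 150 with 1 array left out, and with signals as deposited it was 85, of which 73 were higher and 12 lower.

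**Figure D1:**
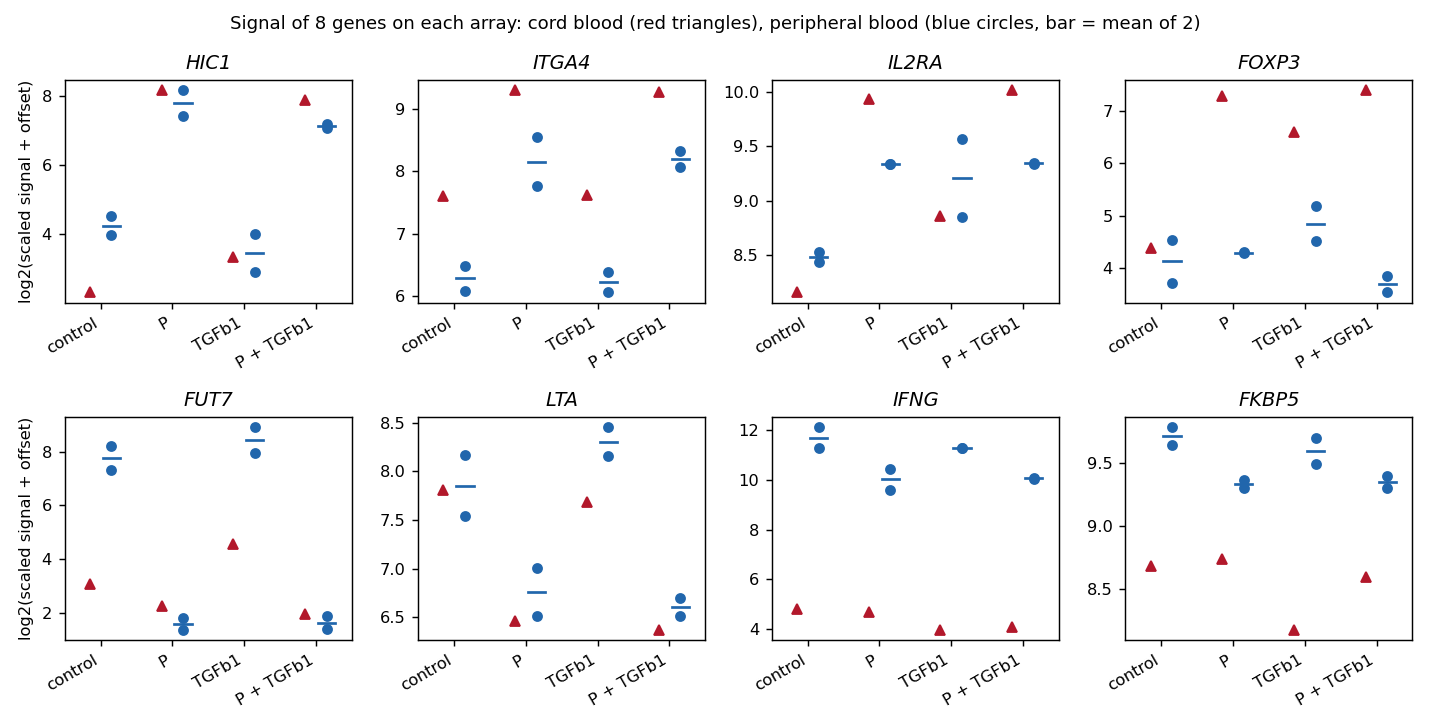
Log2 signal (scaled signal plus offset) of 8 genes on each of the 12 arrays by treatment, with cord blood as red triangles, peripheral blood as blue circles and the mean of 2 peripheral arrays as a bar. HIC1 and ITGA4 were higher and LTA lower with progesterone (P) in both bloods, FOXP3 was higher with progesterone on the cord arrays, and FKBP5 differed by -0.13 ± 0.14.

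The progesterone difference was then read separately without and with TGFb1, 3 arrays against 3. Without TGFb1 9 genes changed, 6 up and 3 down, and in TGFb1 9 changed, 6 up and 3 down. HIC1 (4.33 and 3.97), LZTFL1 (3.03 and 3.15), ITGA4 (1.81 and 1.87) and DHRS3, a retinal reductase (1.41 and 1.55), rose in both settings, and BCAT1 fell in both (-1.71 and -1.39). Independent lists of these lengths would share 0.00302 rising genes, against 4 observed. That expectation is too low, since both lists came from the same fit with a shared variance per gene, which favours overlap. IGHM rose by 1.64 without TGFb1 and differed by 0.24 in it (interaction -1.40 ± 0.32, adjusted p = 0.998), and FUT7 fell by 5.38 in TGFb1 and differed by -4.37 without it. The other genes were BATF3, CXCL10 and LAIR1 without TGFb1 and EVI5, FBP1 and LTA in it; DHRS3, CXCL10, LAIR1 and FBP1 were named after their values were seen. With TGFb1 the split was 7 up and 2 down after quantile normalization and 10 up and 1 down with signals as deposited. The numbers of genes were 5 and 1 without a variance trend, and 5 and 3 without both arrays that stood apart.

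Progesterone and TGFb1 together against neither changed 6 genes, 5 up and 1 down. They were HIC1 (3.79 ± 0.47, adjusted p = 0.0046), LZTFL1 (2.90), ITGA4 (1.84), LAIR1, an inhibitory collagen receptor (1.72), and DHRS3 (1.43), which rose, and BCAT1, which fell by 1.81; LAIR1 and DHRS3 were again named after their values were seen. After quantile normalization there were 9, 6 up and 3 down, and 0 without a variance trend.

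With TGFb1, 0 genes passed in limma, with 115 at an unadjusted p under 0.05 against 597 expected by chance. Without progesterone 0 genes passed and 267 had such a p. Both numbers lie under that expectation, so these p-values may have been too large, for a reason that was not tested. The same holds for both interactions with TGFb1 below. The 0 genes therefore do not show that TGFb1 had no effect. The TGFb response genes, direct targets of its receptor, were not higher as a list (22 measured, median 0.08, camera adjusted p = 0.649), and the feedback inhibitor SMAD7 differed by -0.04 ± 0.19 and the integrin chain ITGAE by -0.01 ± 0.23. FOXP3 differed by 0.43 ± 0.38 and IL2RA by 0.38 ± 0.18 (higher in 6 of 6 pairs, adjusted p = 1). As values and not as changes, the highest test statistics among genes higher in all 6 pairs belonged to F2R, a thrombin receptor (1.53), MUC6 (1.06), YBX2 (0.97), FGD2 (0.87) and RELL2 (0.45), and the lowest to SNX11 (-0.39), PELP1 (-0.52), ZKSCAN3 (-0.81), PER3 (-0.95) and ATP6V1E2 (-0.96).

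Small shifts passed by camera in 3 lists with TGFb1: glycolysis and hypoxia genes (median 0.11, adjusted p = 0.00936; adjusted p = 0.752 with an estimated correlation), interferon response genes (0.14, adjusted p = 0.0095; adjusted p = 0.788 with an estimated correlation) and Treg genes (0.14, adjusted p = 0.0417; adjusted p = 0.788 with an estimated correlation). Of their members 0 passed in limma, over all genes or adjusted over the list alone, and 0 lists passed by fry. With signals as deposited their medians were -0.04, -0.00 and -0.01, against a shift of all genes of -0.15. The progesterone by TGFb1 interaction gave 0 genes in limma (374 at an unadjusted p under 0.05). Its highest statistics among genes of one direction in all 3 sets were FGF6 (3.02), TTF2 (1.92), THAP6 (1.43), SLK (1.35) and PAK1IP1 (1.247), and its lowest STING1 (-1.10), FBXW5 (-1.10), SBF1 (-1.22), PHKG2 (-1.30) and IGHM, as values only.

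The series also set cord against peripheral blood T cells. Between them 1614 genes differed, 748 higher and 866 lower in cord blood. IKZF2, the transcription factor Helios, was higher in cord cells by 6.03 ± 0.34 (adjusted p = 5.41e-08), and IGF2BP3, a fetal RNA-binding protein, by 5.28 ± 0.43. IFNG, the cytokine of Th1 cells, was lower with a difference of -6.38 ± 0.27 (adjusted p = 3.68e-09), with a mean signal of 19.5 ± 6.03 (SD, n = 4) in cord and 2023 ± 1211 (SD, n = 8) in peripheral cultures. IL21 differed by -4.85 ± 0.28. For each gene named here as higher or lower, unless said otherwise, the cord array lay beyond both peripheral arrays in 4 of 4 treatments.

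Other large increases in cord cells were in IGFBP2 (4.91), the transcription factor SOX4 (4.86), the surface lectin CD93 (4.76), CFAP95 (4.13), the phosphodiesterase PDE7B (4.05), the prostaglandin-degrading enzyme HPGD (3.92), the soluble collagen receptor LAIR2 (3.83) and LRRN3, a marker of recently formed T cells (3.54). The largest decreases, beside IFNG and IL21, were in the fatty acid receptor GPR84 (-4.84), the cadherin CDH3 (-4.46), the chemokine CXCL8 (-4.34), PRR34-AS1 (-4.30), TSHZ2 (-4.07), the tryptophan-degrading enzyme IDO1 (-3.93), GZMK (-3.73) and TBX21 (-3.69). Of 10 fetal developmental genes 4 were higher, IKZF2, IGF2BP3, SOX4 and TOX (3.27), and 5 higher and 1 lower adjusted over the list alone (median 0.45, camera adjusted p = 5.76e-04; adjusted p = 0.114 with an estimated correlation). Of 15 Th1 genes 8 were lower, among them IFNG, TBX21, the chemokine CCL4 (-3.66) and the IL-12 receptor chain IL12RB2 (-3.46), and 8 adjusted over the list alone (median -0.79, camera adjusted p = 9.22e-07; adjusted p = 0.0827 with an estimated correlation). Of 13 cytotoxic genes 5 were lower, with GZMB (-2.84), GZMH (-2.60) and CTSW (-1.95) beside GZMK, and 1 higher (camera adjusted p = 0.0257; adjusted p = 0.341 with an estimated correlation); adjusted over the list alone the numbers were 5 and 2. Of 15 Th17 genes 5 were lower, with IL21, IL23R (-2.53) and BATF (-1.08), and 1 higher, IL6ST (1.01), also adjusted over the list alone (camera adjusted p = 0.0425; adjusted p = 0.23 with an estimated correlation). The cytokine IL17F, at low signal, differed by -2.30 ± 0.57 (adjusted p = 0.0145).

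Some lists of signalling and stress genes were lower in cord cells as well, while the heat shock list did not pass (camera adjusted p = 0.0718). Of its 11 measured genes 2 were lower and 1 higher, HSPB1 (1.15). Of 24 interferon response genes 15 were lower, such as HERC5 (-2.57), IFI44 (-1.90), OASL (-1.87) and IFIT2 (-1.51), and 18 adjusted over the list alone (median -1.10, camera adjusted p = 1.04e-10; adjusted p = 0.251 with an estimated correlation). Of 20 IL-2 and STAT5 response genes 11 were lower, such as SOCS3 (-3.13), OSM (-2.40) and LIF (-2.25); adjusted over the list alone 11 were lower and 1 higher (median -0.75, camera adjusted p = 1.61e-05; adjusted p = 0.114 with an estimated correlation). Amino acid and unfolded protein stress genes were lower in 7 of 20, such as ATF3 (-2.37), XBP1 (-2.03) and CEBPB (-2.00), and in 13 adjusted over the list alone (median -0.57, camera adjusted p = 1.18e-07; adjusted p = 0.197 with an estimated correlation). TCR activation genes, induced by antigen receptor signals, were lower in 7 of 22, with IL2 (-1.96), JUN (-1.64) and JUNB (-1.34), and higher in 1, XCL1 (2.25), and lower in 9 and higher in 2 adjusted over the list alone (camera adjusted p = 0.00642; adjusted p = 0.197 with an estimated correlation). Of 23 steroid receptor response genes 11 were lower and 4 higher, and 13 and 5 adjusted over the list alone (median -0.75, camera adjusted p = 2.63e-04; adjusted p = 0.114 with an estimated correlation). Those lower included metallothioneins, zinc-binding proteins, such as MT1X (-2.13) and MT2A (-2.26), and FKBP5 (-0.95), whereas TSC22D3 was higher (1.58). Cell cycle genes were lower in 4 of 32, with CDC45 (-0.80) and RRM2 (-0.47); adjusted over the list alone 8 were lower and 2 higher (median -0.32, camera adjusted p = 0.00569; adjusted p = 0.474 with an estimated correlation).

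Lists that did not pass by camera held single genes that differed. Among 21 Treg genes 7 were higher and 4 lower, also adjusted over the list alone. FOXP3 was higher (2.18 ± 0.41, adjusted p = 0.00233), with the cord array beyond both peripheral arrays in 3 of 4 treatments, and LAG3 (-1.98) and ICOS (-0.87) were lower. GATA3 (0.89) and the cytokine IL13 (1.31) of Th2 cells were higher, as were KLF2 (1.38), a regulator of T cell egress, ITGA4 (1.24) and the chemokine receptor CCR2 (3.40), while CXCR3 was lower (-2.56). The mineralocorticoid receptor NR3C2 was lower (-3.17) with a mean signal of 0.535 in cord cultures, and NR3C1, the glucocorticoid receptor, differed by 0.32 ± 0.15 (adjusted p = 0.165). IL2RA (0.15), CTLA4 (-0.52), ITGAE (-0.18), SMAD7 (0.28) and MKI67 (0.37) did not pass. The desaturase FADS2 (0.48) and the cholesterol synthesis enzyme IDI1 (-0.56) passed, but turned sign when all probe sets of the gene were averaged (-0.12 and 0.05).

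Markers of other cells moved with the blood source and stand beside all of these groups. Lower in cord cultures were the monocyte genes S100A9 (-3.04), LYZ (-1.65) and TYROBP (-1.37), the dendritic cell chemokines CCL17 (-1.49) and CCL22 (-1.37), the mast cell gene TPSAB1 (-1.86), the haemoglobin gene HBB (-1.96), the platelet gene ITGA2B (-1.45) and the progenitor gene GATA2 (-1.21). IGHM (2.72), the natural killer receptor NCR3 (1.79) and the CD8 chain CD8B (1.21) were higher. For LYZ and CCL22 the cord array was not beyond both peripheral arrays in every treatment. Of the 11 marker lists 0 passed by camera, the lowest adjusted p being 0.051 for dendritic cells, and 8 passed by fry. Of 32 lists 10 passed by camera, 0 of them with an estimated correlation, and 20 by fry. With signals as deposited 712 genes differed, and with 1 array left out 888 to 1806.

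**Figure D2:**
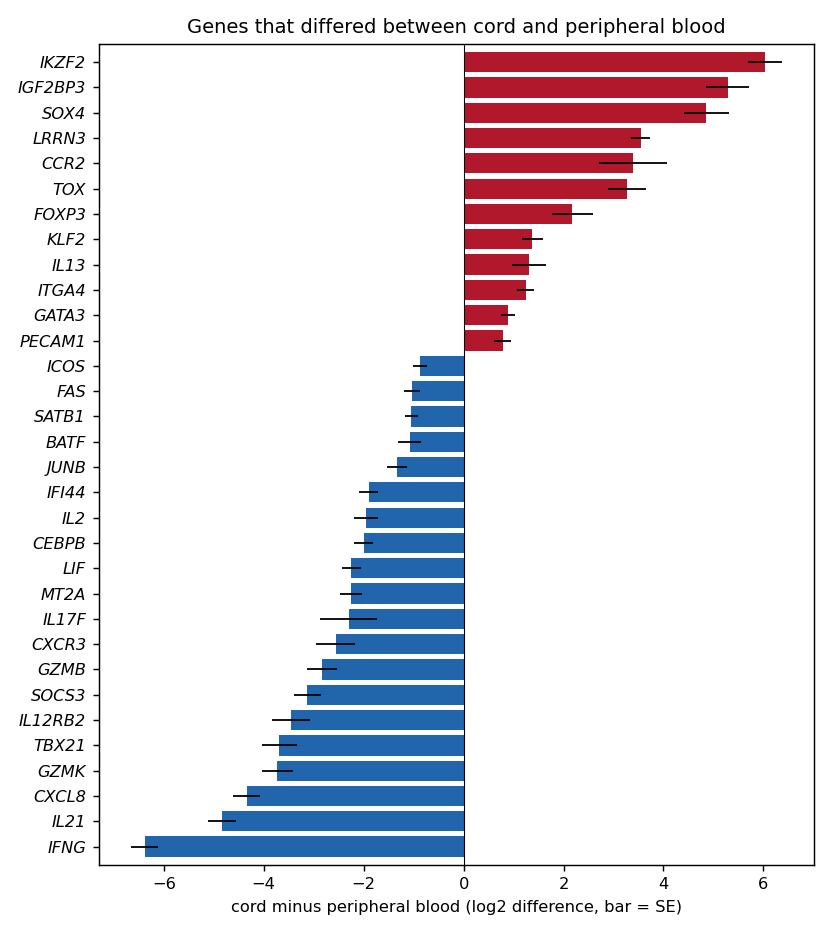
Log2 difference between cord and peripheral blood T cells (cord minus peripheral, bars, with SE as lines) of 32 genes past the threshold in limma, red where higher in cord blood and blue where lower. The values run from -6.38 for IFNG to 6.03 for IKZF2.

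Whether progesterone acted alike in both bloods was tested by their interaction, which is positive where the difference was more upward in cord blood. It held for 67 genes, 57 positive and 10 negative. CCR9, the chemokine receptor of gut homing, rose by 7.27 ± 0.77 in cord cells and differed by 0.72 ± 0.55 in peripheral cells (interaction 6.55 ± 0.95, adjusted p = 0.0069). Its mean signal was 471 with progesterone and 1.13 without in cord cells, and 6.61 and 3.98 in peripheral cells. All but the 471 lay under the filter level of 9.38. IFI27, an interferon-induced gene, rose by 6.45 ± 0.35 and differed by 0.75 ± 0.25 (interaction 5.70 ± 0.43, adjusted p = 4.09e-05). SOCS2, a feedback inhibitor of cytokine signals, fell by 2.77 ± 0.27 in cord cells and differed by 0.84 ± 0.19 in peripheral cells (interaction -3.61 ± 0.33, adjusted p = 2.18e-04).

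For every gene named in this comparison that passed, the cord difference lay beyond both peripheral differences with and without TGFb1. The other large positive interactions were in CLIC3 (5.10), CSF2RB, the shared receptor chain of myeloid cytokines (4.54), TMT1A (4.49), ASB2 (4.47), the ATP-gated channel P2RX5 (4.46), NAPSA (4.25) and its close paralogue NAPSB (4.17), and in FUT7 (4.73), which fell in peripheral cells from a mean signal of 292 to 1.13 and was low in cord cells throughout (14.3 and 2.36). The negative ones were in SFN (-2.83), LPAR6 (-2.80), SCML1 (-2.76), C1orf162 (-2.51), CISH (-2.40), the growth factor HBEGF (-2.29), MAD1L1 (-1.86), PCED1B (-1.80) and MDFIC (-1.45). Other probe sets gave smaller interactions for NAPSB (0.90 ± 0.61), TMT1A (1.78 ± 0.86 and 0.73 ± 1.13) and FUT7 (1.81 ± 0.75), whereas that of ASB2 gave 4.65 ± 0.94. NAPSB had a mean signal of only 0.769 in cord cells without progesterone.

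Interferon response genes rose further in cord cells than in peripheral cells: 9 of 24 passed, such as USP18 (2.29), IFIT1 (2.24) and RSAD2 (1.95) beside IFI27, and 20 adjusted over the list alone (median 1.53, camera adjusted p = 1.37e-29; adjusted p = 0.0757 with an estimated correlation; fry adjusted p = 0.0141). Cord cells started lower. IFIT1 had mean signals of 69.5 without and 413 with progesterone in cord cells, against 394 and 538 in peripheral cells. USP18 (65.6 and 392, against 406 and 499) and RSAD2 (95.7 and 389, against 648 and 687) also stayed under the peripheral level. IFI27 rose past it (44.8 and 3448, against 271 and 442). The lower mean of this list in cord cells over all treatments and its interaction may share that low start. Within cord cells 16 of the 24 rose, and 22 adjusted over the list alone, and in peripheral cells 0 passed in limma either way. The list was still higher there in 21 of 24 genes by a small margin (median 0.18, camera adjusted p = 5.56e-04; adjusted p = 0.424 with an estimated correlation). Treg genes also rose further in cord cells: 3 of 21 passed, CTLA4 (2.11 ± 0.35, adjusted p = 0.018), the co-stimulatory receptor TNFRSF18 (2.06) and the cytokine subunit EBI3 (3.09), and 10 adjusted over the list alone (median 1.01, camera adjusted p = 1.2e-08; adjusted p = 0.0347 with an estimated correlation; fry adjusted p = 2.94e-04). Within cord cells 8 of the 21 rose, FOXP3 (1.84 ± 0.40, adjusted p = 0.0231), CTLA4 (2.01) and IL2RA (1.47) among them; in peripheral cells 0 passed in limma, and FOXP3 differed by -0.49 ± 0.28. The interaction of FOXP3 was 2.34 ± 0.49 (adjusted p = 0.053), and that of IL2RA 0.97 ± 0.32 (adjusted p = 0.271). For the other IL2RA probe set the interaction was 0.08 ± 0.50. TNFRSF18 had mean signals of 36.5 without and 166 with progesterone in cord cells, against 168 and 177 in peripheral cells. With progesterone, CTLA4 (115 and 431, against 321 and 297) and EBI3 (15.9 and 95.0, against 92.0 and 58.6) ended above the peripheral level.

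Among IL-2 and STAT5 response genes SOCS3 was positive (1.72) and SOCS2 and CISH were negative; adjusted over the list alone 4 were positive and 6 negative, and the list was lower (median -0.54, camera adjusted p = 0.0295; adjusted p = 0.526 with an estimated correlation). TCR activation genes were higher (median 0.60, camera adjusted p = 0.0295; adjusted p = 0.307 with an estimated correlation), with 1 of 22 past the threshold, the phosphatase DUSP2 (1.65), and 2 positive and 1 negative adjusted over the list alone. Naive and central memory genes were lower (median -0.45, camera adjusted p = 0.00595; adjusted p = 0.428 with an estimated correlation) with 0 of 17 past the threshold in limma; adjusted over the list alone CCR7 (1.33) was positive and MAL (-1.90) negative. Cell cycle genes were lower (median -0.30, camera adjusted p = 0.00595; adjusted p = 0.526 with an estimated correlation) with 0 past the threshold either way. Amino acid and unfolded protein stress genes were higher (median 0.42, camera adjusted p = 0.00884, adjusted p = 0.526 with an estimated correlation). With signals as deposited their median was -0.03, against -0.45 for all genes (camera adjusted p = 0.0462). In limma 0 of 20 passed, and adjusted over the list alone SESN2 (1.26) was positive and XBP1 (-1.48) negative. The Th1 genes IL18RAP (2.55) and IL12RB2 (2.54), CD38, an NAD-consuming surface enzyme (3.17), and LDLRAD4, a TGFb target (1.78), were positive in lists that did not pass. Other LDLRAD4 probe sets had interactions of 0.40 ± 0.63, 1.29 ± 0.57 and 1.38 ± 0.84. IFNG fell by 1.44 ± 0.23 in peripheral cells (adjusted p = 0.0185) and differed by 0.00 ± 0.32 in cord cells, where its signal was low (interaction 1.45, adjusted p = 0.147).

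Single markers of other cells moved too. The B cell gene CD79A (2.74), the dendritic cell chemokine CCL22 (2.56) and FCER1G, a signalling chain of natural killer and myeloid cells (2.21), had positive interactions, while 0 of 11 marker lists passed by camera, the lowest adjusted p being 0.0599 for CD8 T cells. Within peripheral cells both measured dendritic cell markers, CCL17 and CCL22, were lower with progesterone as a list (median -0.998, camera adjusted p = 0.00143; adjusted p = 0.273 with an estimated correlation). The 6 B cell markers were higher there (median 0.15, camera adjusted p = 0.0361; adjusted p = 0.295 with an estimated correlation), with 0 members of either list past the threshold over all genes in limma. Adjusted over the list alone, 1 dendritic cell marker fell and 2 B cell markers rose. In all, 9 of 32 lists passed by camera within peripheral cells, 0 of them with an estimated correlation and 0 by fry. Within cord cells 5 passed, 1 of them with an estimated correlation and 3 by fry.

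In cord cells alone 415 genes changed with progesterone, 291 up and 124 down, and in peripheral cells alone 23, of which 11 rose and 12 fell. The cord number was 18 to 535 with 1 array left out (18 without cord progesterone, 20 without cord control), 115 with signals as deposited and 991 without both arrays that stood apart. The lists shared 8 rising and 3 falling genes, against 0.268 and 0.125 for independent lists of these lengths. Both lists came from the same fit with a shared variance per gene, which favours overlap, so these expectations are too low. The shared rising genes were HIC1, NAPSA, LZTFL1, QPRT, EVI5, ITGA4, VDR and DHRS3, and the shared falling genes BCAT1, TGFBR3 and LTA; DHRS3 was chosen after its values were seen. Of the genes that rose in cord cells, 80.1% had the same sign in peripheral cells, with medians of 1.88 and 0.29. Peripheral cells changed further in FUT7 (-6.46), EPAS1, a hypoxia-responsive factor (-1.99, interaction 3.19), SLAMF7 (-1.90), GZMK (-1.78), PTGER2, a prostaglandin receptor (1.73), and LAIR1 (1.85); EPAS1, SLAMF7, PTGER2 and LAIR1 were chosen after their values were seen, and only FUT7 and EPAS1 of these passed the interaction test.

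The cord values rest on 1 array per treatment, assumed to vary like the peripheral arrays, and leaving out a cord array brought the 67 interaction genes down to 6 or 7. Without both arrays that stood apart the interaction held for 234 genes, and with signals as deposited for 14, 10 positive and 4 negative, where the 23 peripheral genes became 8, 7 up and 1 down. The blood by TGFb1 interaction gave 0 genes in limma (147 at an unadjusted p under 0.05), with DGCR5 (2.71), LINC02610 (2.64), GZMK (1.52), B4GALT4 (1.28) and MIDN (1.10) highest and ADARB2-AS1 (-2.06), ITGA3 (-2.13), PCOLCE-AS1 (-2.28), CXCR3 (-2.40) and KLK12 (-2.79) lowest, as values only.

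**Figure D3:**
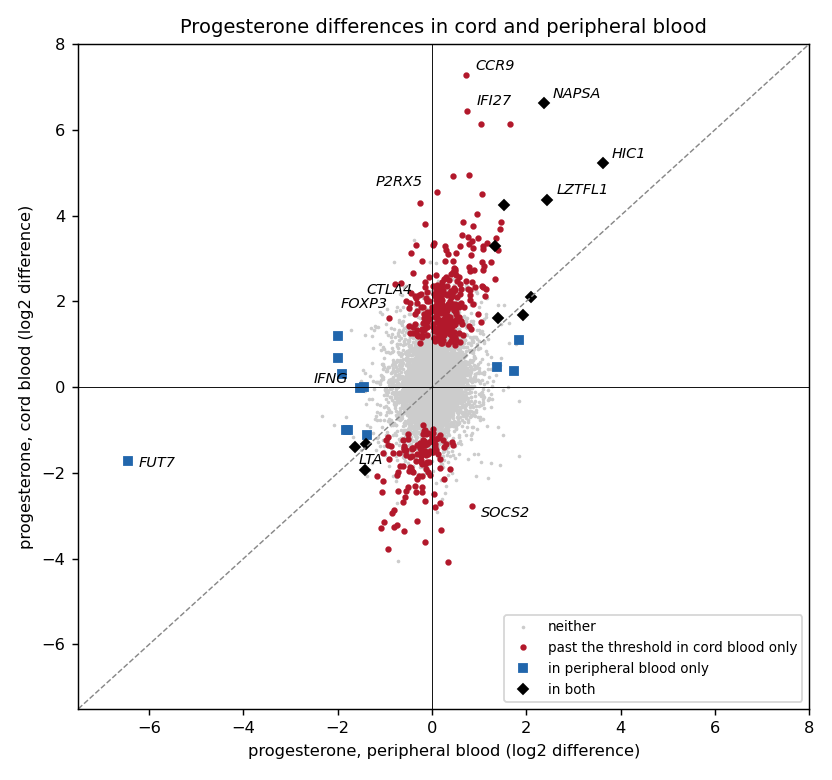
Log2 difference with progesterone of each of 11934 genes in peripheral blood (horizontal) and cord blood (vertical), with genes past the threshold in cord blood only in red, in peripheral blood only as blue squares and in both as black diamonds. Most red points lie near 0 on the horizontal axis, and HIC1 lies at 3.62 and 5.22.

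**Figure D4:**
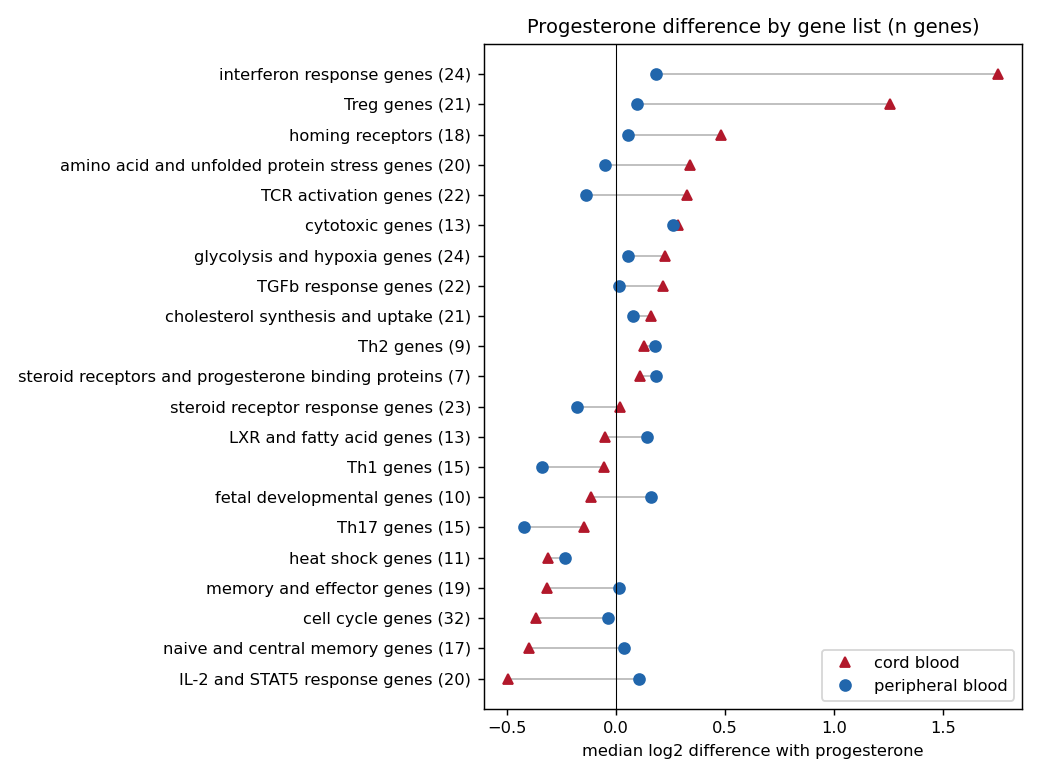
Median log2 difference with progesterone of the measured members of each of 21 gene lists (number of genes in brackets), in cord blood (red triangles) and in peripheral blood (blue circles). The interferon response genes (1.75 and 0.18) and the Treg genes (1.254 and 0.10) lie farthest apart.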

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

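The tests of both arrays that stood apart, of the single cord culture, of RNA length and of exchanged labels and the comparison of culture sets under one error term were chosen only after the result was seen; the test of lone culture sets and the other splits of the arrays were planned before their results.

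The progesterone difference was itself different between the bloods for 67 genes and 7 gene lists, by the interaction test. The genes of the naming rule with a more upward difference in cord blood were CCR9 (6.55), IFI27 (5.70), CLIC3 (5.10), FUT7 (4.73), CSF2RB (4.54), TMT1A (4.49), ASB2 (4.47), P2RX5 (4.46), NAPSA (4.25), NAPSB (4.17), CD38 (3.17), EBI3 (3.09), CD79A (2.74), CCL22 (2.56), IL18RAP (2.55), IL12RB2 (2.54), USP18 (2.29), IFIT1 (2.24), FCER1G (2.21), CTLA4 (2.11), TNFRSF18 (2.06), RSAD2 (1.95), LDLRAD4 (1.78), SOCS3 (1.72) and DUSP2 (1.65), as log2 differences of differences. Those with a more downward one were MDFIC (-1.45), PCED1B (-1.80), MAD1L1 (-1.86), HBEGF (-2.29), CISH (-2.40), C1orf162 (-2.51), SCML1 (-2.76), LPAR6 (-2.80), SFN (-2.83) and SOCS2 (-3.61).

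All of these but FUT7, which fell further in peripheral blood (-6.46, against -1.73 in cord blood, where its signal was low), differed more in cord blood. The tables argue in part against 1 technical explanation for that, and in part against another. Both peripheral arrays that stood apart could have blurred the peripheral difference, but 67 of the 67 genes stayed past the threshold without them. That count argues against blurring as the whole of the interaction. It does not show whether the peripheral differences grew, and more genes passed the interaction test without these arrays. A culture-to-culture spread of the size seen between both peripheral sets is argued against for the large differences alone: with a progesterone difference per set and one error term, limma called 0 genes between the peripheral sets, against 137 and 272 between the cord set and each of them. At an unadjusted p under 0.05 the numbers were 1903, 1424 and 1956, so smaller differences were as widespread between the peripheral sets, and for them this spread stays open. The planned count with a peripheral set as the lone set, 0 at most, decided nothing, since the median standard error of the 67 genes was then 1.07 and 0.997, against 0.386. Also open is that a property of the single cord culture, rather than of cord blood, may lie behind them, since there was only 1 cord culture set, and the biological difference between the bloods was untested beyond that set.

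Of 100 splits of single arrays 2 gave as many as the 67 genes, the real one included, with 96 the highest other. These splits do not decide about chance, since regrouping the blood labels left the difference between the bloods (1614 genes) in the error term. That can lower the counts of the other splits. The splits also treat arrays as exchangeable, while the cord arrays are 1 of only 3 culture sets. Splits of sets are too few for a share under 0.05. The highest split put the cord arrays with progesterone and with TGFb1 and both peripheral controls into the group of 4, and the same split gave 489 genes for the blood by TGFb1 interaction, where the real value was 0 and 100 of 100 splits gave as many. Such a count points to a structure of the samples, whose nature was not tested. Chance is not excluded for the number of interaction lists (7, highest other 10, 22 of 100 splits).

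For the other comparisons, the real split alone reached the real count for progesterone (109 genes, highest other 17, 1 of 100 splits). The same held for cord against peripheral blood (1614, highest other 808, 1 of 100, with the same limit of 1 cord set). So the other divisions of single arrays drawn did not give such counts. Chance between culture sets is not excluded, since the splits treat arrays as exchangeable. Regrouping also left the real difference in the error term, which can lower the counts of the other splits. Nor is chance excluded for the number of lists with progesterone (6, highest other 11, 22 of 100), with TGFb1 (3, highest other 10, 61 of 100) or between the bloods (10, highest other 12, 6 of 100). For TGFb1 and for the progesterone by TGFb1 interaction the real value was 0, so that 100 of 100 splits gave as many, with 133 the highest other for each. The TGFb1 split with 133 genes put all 4 peripheral arrays numbered 2 together with both cord arrays with progesterone, and so follows a number shared by arrays; with the culture sets as a block the TGFb1 count was 0. For progesterone without TGFb1 (9, highest other 0, 1 of 10 splits), in TGFb1 (9, highest other 0, 1 of 10), both together (6, highest other 0, 1 of 10) and TGFb1 without progesterone (0, highest other 0, 10 of 10), the splits are too few for a share under 0.05. In peripheral blood 2 of 34 splits gave as many as the real 23 genes, so chance is not excluded; the highest other, 69, parted the arrays by replicate number, and with the culture sets as a block the count was 24.

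A second pattern is that 2 peripheral arrays, progesterone 1 and TGFb1 2, stood apart from the other 10. Exchanged labels are excluded: over 147 genes, the progesterone score of the array labelled progesterone 1 was 96.1% of that of the other peripheral progesterone arrays, and that of TGFb1 2 was 19.4%. Labelled RNA of another length distribution stays open. The lower actin 5′ to 3′ ratio on these arrays, 0.971, lay above the 0.639 that was highest elsewhere. That ratio is the measure on which they stood apart, so it cannot decide the cause. The GAPDH ratio lay between 1.10 and 1.22 on all arrays. No biological explanation was tested.

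Probe sets assigned to no single gene took no part in the comparisons and also held signal past the threshold: of 3578 tested, 5 changed with progesterone, 10 in cord blood and 3 in peripheral blood.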

How the results depend on the processing

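Signals as deposited, cyclic loess, leaving out both arrays that stood apart and peripheral arrays alone with the block were chosen after seeing the data; the other alternatives were planned. The 168 values of named genes past the threshold stayed on their side in 1808 of 1963 results under other settings, with 153 weaker and 2 reversed, and in 1656 of 2016 with 1 array left out, with 360 weaker. Reversed with the probe sets of a gene averaged were FADS2 (-0.12) and IDI1 (0.053) between the bloods, because other probe sets of the gene differ in direction. Of the 160 other probe sets of named genes past the threshold, 10 pointed the opposite way, 2 of them at an unadjusted p under 0.05. Genes of low signal are limited by background. The counts for TGFb1, TGFb1 without progesterone and both other interactions were 0 in limma under every alternative run for them. The interaction model was run for progesterone, TGFb1, their interaction and the bloods, and peripheral arrays alone for progesterone in peripheral blood. Genes below a stricter filter have no value there.

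Without a variance trend the counts were 25 for progesterone, 5 without TGFb1, 1 in TGFb1, 0 for both together, 25 for the blood by progesterone interaction and 11 in peripheral blood. With the interaction model 246 genes changed with progesterone. Without a signal filter 5 changed in TGFb1 and 0 lists passed for TGFb1. With probe sets averaged 1 changed with both together. With signals as deposited the counts were 4 without TGFb1, 712 between the bloods, 14 for the interaction, 115 in cord blood and 8 in peripheral blood, and 10 lists passed for progesterone and 11 for the interaction. That scaling shifted the median of all genes by 0.11 for progesterone, -0.45 for the interaction, -0.19 in cord blood and 0.26 in peripheral blood. Without both arrays that stood apart the counts were 5 without TGFb1, 3 in TGFb1, 234 for the interaction and 991 in cord blood. By camera with an estimated correlation 0 lists passed for progesterone, 0 for TGFb1, 0 between the bloods and 1 for the interaction, and by fry 0, 0, 20 and 2. The cause was not tested, except that fewer arrays or more genes tested lower the power.

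With 1 array left out, progesterone gave 27 to 150 genes. It gave 42 without cord control, 31 without cord progesterone, 32 without cord TGFb1, 27 without cord progesterone and TGFb1, 42 without the peripheral array 1 of both together and 69 without peripheral control 2. Without TGFb1 the range was 3 to 12, with 4 without cord control, cord progesterone or peripheral control 2 and 3 without peripheral progesterone 1. In TGFb1 it was 3 to 9, with 5 without cord TGFb1, peripheral control 1 or peripheral progesterone 1, 4 without cord progesterone and TGFb1, its peripheral array 1 or peripheral TGFb1 2, and 3 without its peripheral array 2. For both together it was 3 to 9, the 3 without the peripheral array 1 of both. Between the bloods it was 888 to 1806, with 1060 without cord control, 995 without cord progesterone and 888 without cord TGFb1.

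For the blood by progesterone interaction the range was 6 to 121, with 6 without cord control or cord progesterone, 7 without either other cord array, 40 and 35 without the peripheral arrays 1 and 2 of both together, 29 without peripheral control 2 and 121 without peripheral TGFb1 2. In cord blood it was 18 to 535, with 20 without control, 18 without progesterone, 60 without TGFb1 and 59 without both together. In peripheral blood it was 9 to 28, with 9 and 11 without the arrays 1 and 2 of both together and 11 without control 2. The lists passing numbered 4 to 9 for progesterone, 8 to 13 between the bloods, 5 to 8 for the interaction and 0 to 7 for TGFb1, with 0 without cord control or cord progesterone and TGFb1, 7 without peripheral control 1 or the peripheral array 1 of both, and 1 without peripheral progesterone 1 or 2.

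The replicate number was tried as a replicate block, of cord 1, peripheral 1 and peripheral 2. Genes of arrays of one number correlated across treatments at -0.17 to 0.37, over 0.1 in 5 of 6 pairs of treatments, across genes, which are not independent replicates, and with only 2 numbers the arrays share a number and no more. With the replicate block the interaction count was 110, progesterone gave 120, progesterone without TGFb1 11, in TGFb1 9, in cord blood 511 and in peripheral blood 24. A random block gave 1410 between the bloods, with an estimated correlation within culture sets of 0.0277. With only 1 cord set, this block cannot separate the blood from the culture set.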

Other observations

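The test of a general steroid receptor response was chosen only after the result was seen; the retinoic acid list and the B cell genes were written down before their values were read, but after the pattern had been noticed.

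Further genes changed with progesterone, named here after their values were seen. Prostaglandin receptors moved apart, with PTGER2 higher (1.28 ± 0.27) and PTGER4 lower (-0.88 ± 0.17), and the cyclic AMP response factor CREM was higher (0.92 ± 0.20). The co-stimulatory ligand TNFSF4 (-1.17 ± 0.25), the chemokine CXCL10 (-1.30 ± 0.19), the ATP receptor P2RX7 (-1.14 ± 0.25) and the glutamine-making enzyme GLUL (-1.01 ± 0.15) were lower, and CD7, a T cell surface protein, was higher (1.01 ± 0.21). In cord blood alone the lipid transport genes ABCA1 (2.37 ± 0.53) and PLTP (2.56 ± 0.60) rose, and SGK1 (-1.70) and ZBTB16 (-2.80), both inducible by glucocorticoids in many cells, fell. Of these last 4 genes none passed the interaction test (adjusted p = 0.211, 0.16, 0.132 and 0.169).

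Signals of 2 genes of the fixed set were too low to be tested: the cytokine IL17A had a mean of 3.56 and the progesterone receptor PGR a mean of 4.54, with a highest value of 9.34. Across genes, which are not independent replicates, the progesterone difference of the cord set correlated with those of the peripheral sets at 0.23 and 0.12, and the peripheral sets with each other at -0.04. Differences of more than 2-fold were seen for 1286 genes in the cord set and for 501 and 739 in the peripheral sets.

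Some of the genes that changed with progesterone have a known link to retinoic acid; they were picked after their values were seen, moved in both directions and are no tested group. HIC1 (4.15), ASB2 (3.15), DHRS3 (1.48), ITGA4 (1.84), PLAAT4 (1.73) and LZTFL1 (3.09) rose, CCR9 (7.27) and CD38 (3.84) rose in cord blood, and FUT7 fell by 4.88, while RARA, a retinoic acid receptor and itself a common target, fell by 1.20. More B cells in the cord cultures are argued against, since the median difference of the abundant B cell genes MS4A1 and CD79B was -0.43, with CD79B at 0.05 ± 0.29 and MS4A1 at a signal of 5.25 with progesterone and 10.7 without. Other B cell genes were higher there, CD79A by 3.51 and IGHM by 0.88 ± 0.27, and B cells in the peripheral cultures, where their list was higher (camera adjusted p = 0.0361), stay open. A general steroid receptor response stays open: its list had a median of -0.13 and FKBP5 was flat, but TSC22D3 rose. A retinoic acid receptor response stays open too. Of the 13 genes of an independent list only CRABP2 (0.10) and STRA6 (0.06) were measured, at low mean signals of 13.9 and 19.2. Their median was 0.0804 and 0 of 2 passed the threshold in limma, which are too few genes to decide. Nothing in the labels names retinoic acid, and the culture medium was not analysed here.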
